A study of Mus musculus with 2 samples.

How the data were processed

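Droplet 3′ single-cell RNA sequencing was done on CD45+ cells of 2 samples, 1 per genotype, each from 5 pooled tumours, with 10000 reads per cell aimed for, per the labels' protocols. The submitters' processing notes name Cell Ranger and mm10, and per the file headers the matrix was written by software version 3.0.2. The deposited values are UMI counts per gene and barcode, not normalised, of a filtered matrix with 33700981 stored entries. All entries were checked on the file to be whole numbers of at least 1. How reads were assigned and whether the libraries were equalised in depth is not given in the sources used here. Barcodes carry only a library number, so each library is reported under that number and no comparison between genotypes was made. The 35 symbols given to more than 1 gene were left out of ratios.

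The design, gene lists, markers and the rule for named genes were fixed before the data were examined. The naming rule was completed after the clusters were seen. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5, marked 0.0139% and 0.021% of barcodes at its automatic threshold and so had not worked, and barcodes scoring above the point that marks the highest 6% were left out instead. Tied scores at that point stayed in, so that 401 barcodes (5.58%) of library 1 and 547 (5.74%) of library 2 were left out. This left 6788 and 8981 barcodes. Counts were scaled to 10000 per barcode and log-transformed, and 2000 highly variable genes, without the functional lists and without mitochondrial, ribosomal and receptor variable genes, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), with no integration. A cluster was named from fixed markers when at least 3 were 2 times above the 25th percentile of clusters and seen in 5% of its barcodes, and stayed unnamed when its 10 leading genes held more markers of another lineage, or when its median UMIs were under 0.333 of its sample's and none of the name's markers was among them. Grouping types by lineage and choosing T cell subtypes from their own markers were added after the clusters were seen. Melanoma-like clusters with median UMIs under 0.5 of their sample's were set apart as low-UMI melanoma-like, a threshold chosen after the data were seen. Cluster 14 scored highest on conventional dendritic markers but had a marker of migratory dendritic cells and none of its own among its leading genes, so it is given by number and counted among immune-like barcodes.

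UMIs were summed per class and library and divided by the class total to give CPM. Levels have exact Poisson intervals, shares exact Clopper-Pearson binomial intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. A limit for a count of 0 is 3 counts. Of 247 genes in 15 functional lists, 245 were found in the matrix. A list gene entered a comparison of classes with at least 50 UMIs over both classes in each library, and counted as higher in a class when its ratio was at least 2 in both libraries. List medians were set among 10000 random lists of the same size matched on expression in 20 bins, using log2 ratios with a pseudocount of 0.5. Named genes of a class comparison are the 12 highest and 12 lowest ratios over both libraries among list genes on the same side of 1 in both, and Rel. Side by side, they are the 12 highest and 12 lowest ratios in monocyte-like barcodes, and 5 of each in other classes with at least 200 barcodes in both libraries, among genes with at least 50 UMIs and at least 20 CPM in 1 library. Other genes and lists of the text come from the fixed lists and were chosen after their values were seen.

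The ratio code was tested on simulated counts for the monocyte-like against macrophage-like comparison over 5443 genes. These were Poisson draws for this comparison only, without variation between barcodes, free RNA or misplaced barcodes. They test the code and counting error, and not the error of the rule in real barcodes or in shallower classes. All 99 genes changed by 4 times and 29.6% of the 98 genes changed by 2 times, which is the threshold itself, passed the ratio rule, as did 0 of 5246 unchanged genes. The 95% intervals held the simulated ratio for 94.3% of unchanged genes, 90.8% of those changed by 2 times and 91.9% of those changed by 4 times, so they were somewhat narrow for changed genes. Alternatives were other filters on barcodes, doublets kept, Leiden resolution 0.6 and 1.5, functional lists left in the clustering genes, means over cells, 10 UMIs per gene, and thinning to 500 UMIs. Leaving out barcodes that copy a barcode of the other library with over 10 times their UMIs, and subtracting melanoma RNA from immune classes in proportion to Pmel, Mlana, Dct and Tyrp1, were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.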

Results

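Viable CD45+ cells, the marker shared by white blood cells, were sorted from B16F10 tumours, a transplantable mouse melanoma, 2 weeks after injection and profiled by droplet 3′ single-cell RNA sequencing. One library came from wild-type mice carrying LysM-cre and one from mice with the Rel gene deleted in myeloid cells by LysM-cre, each from 5 pooled tumours. Rel encodes c-Rel, a subunit of the transcription factor NF-kB. Both libraries were in 1 matrix of 18252 barcodes and 31053 genes, in which a number after each barcode, 1 or 2, gave the library. Nothing in the sources used here tied that number to a genotype, so the libraries are called library 1 and library 2, no genotype was assigned and no effect of the deletion was read. Library 1 held 7688 barcodes and 49129318 UMIs, with a median of 1588 UMIs per barcode. Library 2 held 10564 barcodes and 73507228 UMIs, with a median of 4290. There was 1 library per genotype, so no test was possible, and all intervals are 95% intervals that cover counting error only.

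Monocyte-like, macrophage-like and CD8 T-like barcodes made up most of the immune-like barcodes in both libraries. Of 2745 immune-like barcodes in library 1, 29.9% were monocyte-like (exact binomial interval 28.2 to 31.6), 13.1% macrophage-like (11.9 to 14.4), 24.7% CD8 T-like (23.1 to 26.3) and 11.9% NK-like (10.7 to 13.1). Of 2493 in library 2, 39.9% were monocyte-like (37.9 to 41.8), 26.0% macrophage-like (24.2 to 27.7), 17.5% CD8 T-like (16.0 to 19.04) and 4.49% NK-like (3.71 to 5.38). Neutrophil-like barcodes were 5.21% (4.41 to 6.11) and 2.97% (2.34 to 3.71). B-like barcodes numbered 147 in library 1 and 9 in library 2. At Leiden resolution 1.5, 131 and 412 of the monocyte-like barcodes fell in a cluster that stayed unnamed and the monocyte-like shares became 26.4% and 27.9%, and with at least 1000 UMIs they were 42.7% and 36.2%. The order of the libraries in this share thus depended on the setting.

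**Figure D1:**
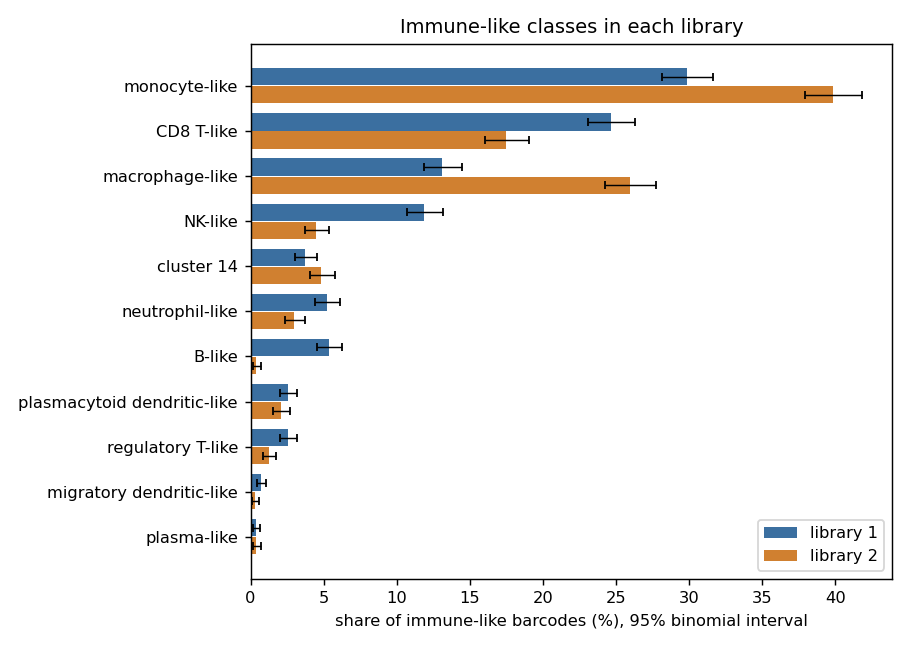
Share of immune-like barcodes (percent, horizontal axis) in each class, with bars for library 1 and library 2 and exact 95% binomial intervals. Monocyte-like barcodes were 29.9% and 39.9%, and macrophage-like barcodes 13.1% and 26.0%.

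Barcodes with melanoma genes were frequent despite the CD45 sort. Barcodes named melanoma-like were 30.3% of the 6788 retained barcodes in library 1 (29.2 to 31.4) and 55.1% of the 8981 in library 2 (54.1 to 56.2), with medians of 17934 and 11611 UMIs. Their clusters passed the naming rule on all 7 melanoma markers, none of which was among the 10 leading genes of a cluster. Histone and cell cycle genes led some of these clusters, Hspb1, Pgf and Ero1l led cluster 2, and interferon-induced genes such as Iigp1 and Igtp led cluster 21. Ptprc, which encodes CD45, was at 2.81 and 2.42 CPM in them, against 692 and 441 CPM in monocyte-like barcodes. A further 25.8% (24.8 to 26.9) and 15.7% (14.95 to 16.5) were melanoma-like with few UMIs, a class separated at a threshold set after the data were seen. Of these low-UMI barcodes, 96.5% in library 1 and 89.5% in library 2 had the sequence of a barcode of the other library that held over 10 times as many UMIs. The libraries shared 3609 barcode sequences in all, and the shallower member of a pair held a median of 3.98% of the deeper one's UMIs in library 1 and 4.75% in library 2. Such copies were 0.109% and 0.882% of immune-like barcodes. With copies left out before clustering, an alternative chosen after seeing the data, the share of all melanoma-like barcodes moved from 56.1% to 42.0% in library 1 and from 70.8% to 64.9% in library 2. No cluster was then named low-UMI melanoma-like, and a cluster of 36 and 95 barcodes with few UMIs, which scored highest on melanoma markers, stayed unnamed (0.739% and 1.27%). Immune-like barcodes were 40.4% and 27.8% of retained barcodes with copies in, and 54.2% and 31.4% without them. The second pair leaves out cluster 14, because a cluster of 103 and 123 barcodes that held most of it stayed unnamed in that setting. Unnamed barcodes were 2.89% and 1.27% with copies in, and 3.06% and 3.44% without them.

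**Figure D2:**
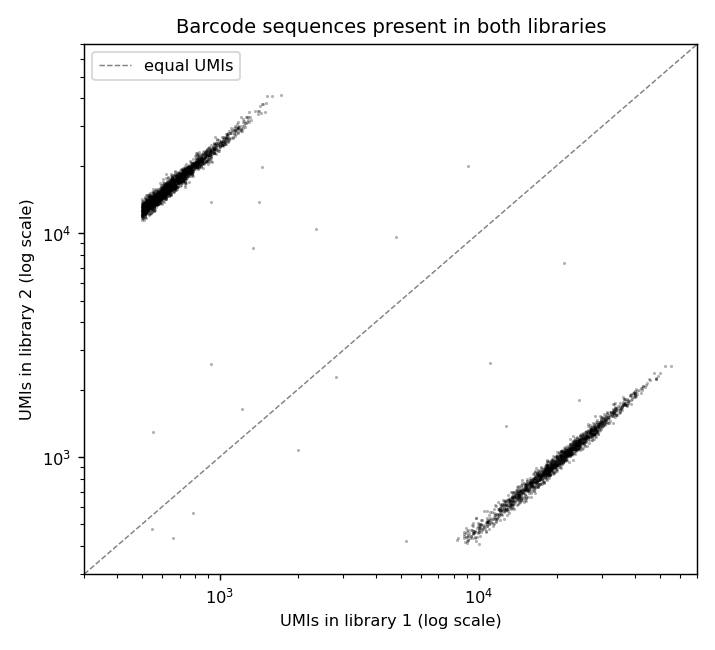
UMIs of each of the 3609 barcode sequences present in both libraries, in library 1 (horizontal, log scale) and library 2 (vertical, log scale), with 1 point per sequence and a dashed line at equal UMIs. Nearly all points lie in 2 narrow bands, at medians of 3.98% and 4.75% of the deeper barcode's UMIs.

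Rel itself was measured first. Rel lies on chromosome 11 from 23736847 to 23770970 on the minus strand of mm10, with 10 exons in its principal transcript, and its 3′ UTR spans 23736847 to 23742267. The sources used here do not say which exons the deletion removes, and counts from the 3′ end need not report on them. In monocyte-like barcodes Rel was at 320 CPM in library 1 (exact Poisson interval 293 to 348, 523 UMIs) and 104 CPM in library 2 (86.5 to 125, 120 UMIs). In macrophage-like barcodes it was at 102 CPM (87.1 to 119) and 21.6 CPM (15.4 to 29.6). In CD8 T-like barcodes it was at 145 CPM (124 to 168) and 162 CPM (132 to 197), in NK-like at 65.6 (40.1 to 101) and 51.1 (16.6 to 119), and in neutrophil-like at 124 (66.3 to 213) and 117 (50.5 to 230). Cluster 14 held 395 (326 to 474) and 275 CPM (213 to 350). Melanoma-like barcodes held 11.4 and 10.4 CPM. The ratio of library 2 to library 1 was 0.326 in monocyte-like (0.265 to 0.399), 0.212 in macrophage-like (0.146 to 0.302) and 1.12 in CD8 T-like barcodes (0.867 to 1.44).

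Before thinning, 40.5% of monocyte-like barcodes in library 1 and 8.15% in library 2 had a Rel UMI. After thinning each barcode to 1000 UMIs, which left out 88 and 463 shallower barcodes, the shares were 27.6% (24.4 to 31.0) and 7.34% (5.27 to 9.90). In macrophage-like barcodes they were 33.1% and 4.79% before thinning and 10.2% (7.21 to 13.9) and 1.88% (0.941 to 3.33) after it. Melanoma-like barcodes, taken as a class that should lack Rel, were at 17.4% and 11.1% before thinning and at 1.88% (1.34 to 2.58) and 1.08% (0.810 to 1.41) after it. In library 2 the intervals of the thinned macrophage-like and melanoma-like shares overlapped, while the CPM in macrophage-like barcodes lay above that in melanoma-like ones.

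**Figure D3:**
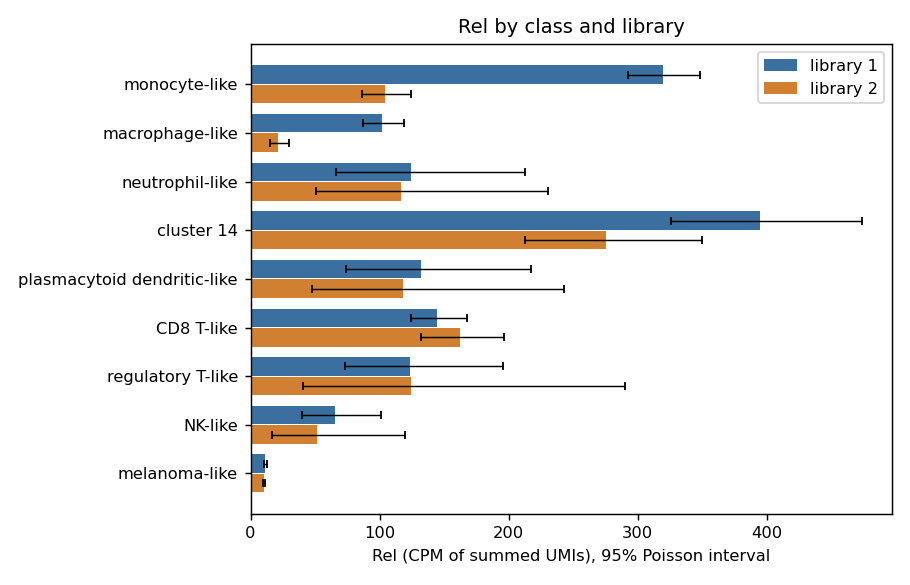
Rel (CPM of summed UMIs, horizontal axis) by class, with bars for library 1 and library 2 and exact 95% Poisson intervals. Monocyte-like barcodes held 320 and 104 CPM, and CD8 T-like barcodes 145 and 162 CPM.

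NF-kB family genes were higher in monocyte-like than in macrophage-like barcodes, and lipid and lysosome genes were lower. Of 182 measured genes of the functional lists, 40 were at least 2 times higher in monocyte-like barcodes in both libraries and 19 at least 2 times higher in macrophage-like ones. Of 16 measured genes of the NF-kB family and its feedback, 10 were higher in monocyte-like barcodes and none in macrophage-like ones. Traf1 was 10.0 times higher (7.85 to 12.96), Nfkbie 4.42 times (3.48 to 5.66) and Rel 3.87 times (3.30 to 4.55). Of 8 inflammatory cytokines, 3 were higher in monocyte-like barcodes and none in macrophage-like ones. Il1b, one of them, was 18.0 times higher (16.8 to 19.3), Ptgs2, a prostaglandin synthase, 7.11 times (5.95 to 8.55) and Cxcl3, a neutrophil-attracting chemokine, 8.74 times (6.05 to 12.99). Of 16 dissociation stress genes, 4 were higher in monocyte-like barcodes and none in macrophage-like ones. The heat shock genes Hspa1a and Hspa1b of that list were 5.18 (4.63 to 5.82) and 7.12 times higher (5.63 to 9.11), and their log2 ratios of 2.37 and 2.83 became 1.53 and 1.77 at resolution 1.5. Of 16 lipid and lysosome genes, 9 were higher in macrophage-like barcodes and none in monocyte-like ones. Ctsd, a lysosomal protease, was 5.48 times higher in macrophage-like barcodes, Abca1, a cholesterol exporter, 5.54 times and Fabp5, a fatty acid carrier, 4.16 times. The chemokine Ccl8 was 98.2 times higher in macrophage-like barcodes, and Mertk, a receptor for dying cells, 7.28 times. Arg1, an enzyme that consumes arginine, was not among them, at 481 against 337 CPM in library 1 and 1254 against 323 CPM in library 2. Of 15 immune suppression genes, 3 were higher in each class. The median log2 ratio was 1.23 for the NF-kB list (percentile 100 among 10000 random lists matched on expression). The NF-kB list did not stand alone. The median was 1.25 for 9 MHC class II genes (percentile 99.985), 0.75 for inflammatory cytokines (percentile 99.82) and 0.65 for dissociation stress (percentile 99.94). It was -1.35 for the lipid and lysosome list (percentile 0) and -0.53 for immune suppression (percentile 0.27).

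**Figure D4:**
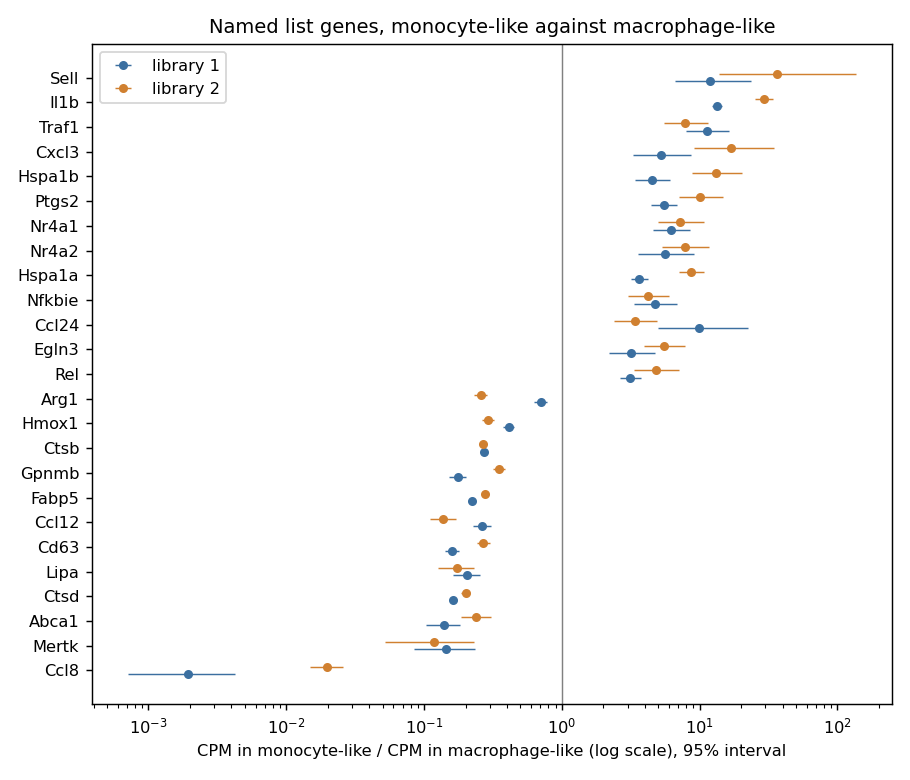
CPM in monocyte-like over CPM in macrophage-like barcodes (horizontal, log scale) for the named list genes, with points for library 1 and library 2 and 95% intervals. Il1b lies far to the right, at 18.0 over both libraries, and Ccl8 far to the left, being 98.2 times higher in macrophage-like barcodes.

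Against neutrophil-like barcodes, several MHC class II and interferon response genes were higher in monocyte-like ones, and chemokines differed in both directions. Of 161 measured list genes, 32 were at least 2 times higher in monocyte-like and 10 in neutrophil-like barcodes in both libraries. Of 8 MHC class II presentation genes, 5 were higher in monocyte-like barcodes, among them H2-DMb1 at 11.2 times (4.799 to 34.7) and Cd86 at 8.93 times (3.04 to 43.5). The median log2 ratio was 3.28, against 0.58 for all genes, but it was 5.44 in library 1 and 1.02 in library 2. Cd74 of this list was at 57.5 CPM (6 UMIs) in neutrophil-like barcodes of library 1 and at 1271 CPM (87 UMIs) in those of library 2. Of 7 interferon response genes, 4 were higher in monocyte-like barcodes and none in neutrophil-like ones, with a median of 1.64 (percentile 98.7). Of 10 MHC class I presentation genes, 3 were higher in monocyte-like barcodes, with a median of 1.06 (percentile 88.4). Gbp2, an interferon-induced GTPase, was 8.04 times higher (4.59 to 15.6). Of 14 chemokines, 4 were higher in monocyte-like and 2 in neutrophil-like barcodes. The chemokine median was 2.47 (percentile 100), but it was 2.98 in library 1 and 0.11 in library 2. Ccl3 was 7.23 times higher in neutrophil-like barcodes, Ddit3 6.24 times, Cd9 5.48 times and Cxcl3 5.01 times. Neutrophil-like barcodes had medians of 630 and 640 UMIs. The 32 genes became 58 with no filter on barcodes, 53 as means over cells and 107 with at least 1000 UMIs. The last setting turned the direction of 10 genes, Ccl3, Cd9 and Cxcl3 among them, and the class named neutrophil-like then held melanoma genes at 94.6% and 85.9% of the melanoma-like level.

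CD8 T-like barcodes carried more checkpoint RNA than NK-like ones and less RNA for some granule proteins. Of 97 measured list genes, 11 were at least 2 times higher in CD8 T-like and 7 in NK-like barcodes in both libraries. Of 11 checkpoint and exhaustion genes, 6 were higher in CD8 T-like barcodes. Lag3 was 14.3 times higher (4.81 to 69.8), Havcr2 6.73 times (3.04 to 18.6) and Tox 3.42 times (1.91 to 6.74). Pdcd1, which encodes PD-1, was at 308 and 271 CPM in CD8 T-like barcodes and at 0 in NK-like ones, where 3 UMIs would be 9.85 and 30.7 CPM. Of 11 cytotoxic effector genes, 4 were higher in NK-like barcodes, with Gzma 28.2 times and Gzmc 4.74 times higher. Ifng alone was higher in CD8 T-like ones, at 6.53 times (3.60 to 13.2). Gzma was also a marker used to name the NK-like class, so its excess partly follows from the name. The Gzmc log2 ratio of -2.24 became -0.80 with copies left out before clustering. NK-like barcodes held 0 copies and went from 326 and 112 to 328 and 110, so removed NK-like copies do not account for that change. In NK-like barcodes of libraries 1 and 2, Gzmc was at 1109 and 5616 CPM and Gzmf had 0 and 810 UMIs. With doublets kept, 18 genes in place of 11 were higher in CD8 T-like barcodes, and with 10 UMIs per gene 15 in place of 7 were higher in NK-like ones. Against regulatory T-like barcodes, of which there were 70 and 31, 16 of 90 list genes were higher in CD8 T-like and 6 in regulatory T-like ones (19 with 10 UMIs per gene). Among them were 10 of 11 cytotoxic effector genes, all higher in CD8 T-like barcodes. Prf1, which encodes perforin, was 13.1 times higher (5.99 to 35.8). Ctla4 was 7.24 times, Icos 2.66 times and Tnfrsf18 2.89 times higher in regulatory T-like barcodes.

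Side by side, monocyte-like and macrophage-like barcodes of library 2 held less inflammatory, interferon and antigen presentation RNA than those of library 1. Lower list medians were not confined to these classes. For library 2 over library 1, neutrophil-like barcodes had a median log2 ratio of -1.59 for 4 inflammatory cytokines and -1.86 for 5 chemokines. Their Rel ratio was 0.939 (0.337 to 2.44). In neutrophil-like barcodes of libraries 1 and 2, Cd74 was at 57.5 and 1271 CPM. Melanoma genes stood there at 3.64% and 9.77% of their melanoma-like level. Whether the make-up of this class differed between the libraries was not tested. Cluster 14 was at -1.14 for 4 interferon response genes but 0.02 for 10 MHC class II genes. The hypoxia and glycolysis list was higher in library 2, at 0.21 in monocyte-like, 0.25 in macrophage-like and 0.20 in CD8 T-like barcodes. In monocyte-like barcodes Tnf was at 661 CPM in library 1 and 93.9 in library 2, a ratio of 0.142 (0.115 to 0.173). Tnfsf9 was at 182 and 26.1 CPM, Il10 at 31.2 and 5.22, Dusp2 at 449 and 83.4, and Nfkbiz, an NF-kB regulator, at 897 and 259. Genes higher in library 2 included S100a8, a neutrophil gene, at 103 and 424 CPM, and the melanoma gene Dct at 121 and 429. Ccl8 was at 3.67 and 48.7 CPM and Mmp12 at 58.1 and 248, both leading genes of the macrophage-like cluster. Whether RNA of macrophage-like cells or a shift towards them added to this was not tested. Melanoma genes stood at 2.58% of their melanoma-like level in monocyte-like barcodes of library 1 and at 8.16% in library 2. The median log2 ratio of library 2 over library 1 was -0.84 for 9 inflammatory cytokines, -0.72 for 20 interferon response genes, -0.72 for 11 MHC class II genes, -0.34 for 16 dissociation stress genes (percentile 0.37) and -0.43 for the NF-kB list (percentile 0.09). Monocyte-like barcodes came from cluster 3 (574 and 826) and cluster 11 (246 and 168). Within cluster 3, looked at after seeing the data, the median was -0.89 for inflammatory cytokines, -0.88 for interferon response, -0.87 for MHC class II and -0.25 for the NF-kB list, and within cluster 11 it was -0.95 for 4 genes, -0.78 for 3, -1.08 for 8 and -0.86 for 11. In macrophage-like barcodes it was -1.04 for 8 inflammatory cytokines, -0.38 for 16 interferon response genes, -1.16 for 9 MHC class II genes and -0.92 for 16 dissociation stress genes. There Arg1 was at 481 and 1254 CPM, a ratio of 2.61 (2.40 to 2.83), Cd74 at 1787 and 609, Egr1 at 630 and 64.4, and Marco, a scavenger receptor, at 6.19 and 86.5. In CD8 T-like barcodes 7 of 9 naive and memory genes were at least 2 times higher in library 1, with Il7r at 420 and 170 CPM. Gzmd was at 60.4 and 650 CPM there, and the neutrophil gene S100a9 at 2.48 and 189, whose log2 ratio of 6.04 became 2.86 with doublets kept. Trdc, a gamma delta T cell marker, was at 44.7 and 6.42 CPM in CD8 T-like barcodes. No CD4 or gamma delta T-like class was named. Cluster 7, with 525 and 305 of the CD8 T-like barcodes, had no Cd8 gene among its leading genes. Whether the mix of T cells in this class differed between the libraries was not tested.

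**Figure D5:**
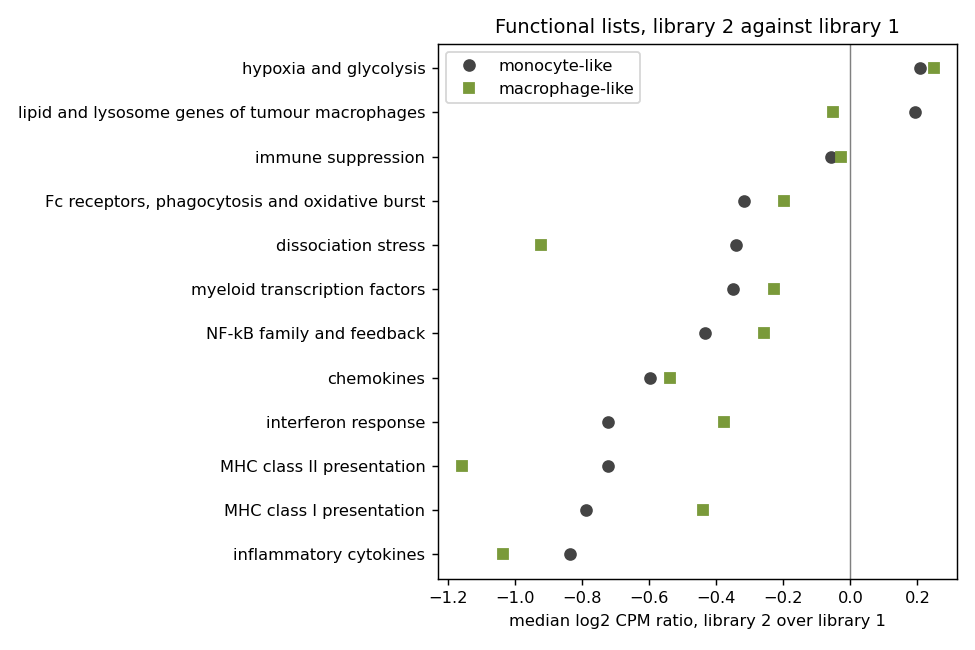
Median log2 ratio of CPM, library 2 over library 1 (horizontal axis), of each functional list with at least 6 measured genes in both classes, with circles for monocyte-like and squares for macrophage-like barcodes. The inflammatory cytokine list lies at -0.84 and -1.04.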

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

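The test of the nearest profile was set before its result was seen, and the tests of depth and of the same library's free RNA were chosen after it. The data held signals outside the planned comparisons: 3609 barcode sequences occurred in both libraries, copies made up 96.5% and 89.5% of low-UMI melanoma-like barcodes, and melanoma-like barcodes with many UMIs were 30.3% and 55.1% of retained barcodes in a CD45 sort.

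For the low-UMI melanoma-like barcodes, free RNA of the same library is argued against: over the 18 genes that differed by 2 times or more between the libraries in melanoma-like barcodes, the median log2 ratio in low-UMI barcodes, signed by that direction, was -0.67, and 18 of 18 went the opposite way. Cck was at 118 and 8.003 CPM in melanoma-like barcodes of libraries 1 and 2 and at 12.7 and 102 CPM in the low-UMI ones. Index swapping between the libraries, in which reads of 1 library carry the other's index, is a candidate explanation: in the library with the lower share, 93.3% of melanoma-like barcodes with at least 20000 UMIs had their sequence in the other library, against at most 16.7% of those with 5000 to 10000. The test set beforehand did not decide: 46.5% of 2952 copies (44.7 to 48.4) were nearest to their own partner among 20 candidates, above the 5% of chance but short of the over 50% that had been set for swapping. No biological explanation was tested for these barcodes.

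No explanation was tested for the melanoma-like barcodes with many UMIs.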

How the results depend on the processing

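Leaving out copies and subtracting melanoma RNA were chosen after seeing the data. Rel CPM in monocyte-like and macrophage-like barcodes, the counts of the monocyte-like against macrophage-like comparison and the NF-kB list medians of library 2 over library 1 stayed within their intervals, or within 1.5 times for counts, under every alternative run. The share of all melanoma-like barcodes (56.1% and 70.8%) became 42.0% and 64.9% without copies, 50.5% and 67.7% with at least 1000 UMIs, 54.6% and 69.8% with doublets kept, 58.9% in library 1 with the functional lists left in, and in library 2 68.8% with at most 5% mitochondrial UMIs and 67.6% with no filter. The monocyte-like share of immune barcodes (29.9% and 39.9%) became 26.4% and 27.9% at resolution 1.5, 42.7% and 36.2% with at least 1000 UMIs, and in library 2 42.2% with at most 5% mitochondrial UMIs and 37.1% with no filter. The 32 list genes higher in monocyte-like than neutrophil-like barcodes became 107 with at least 1000 UMIs, 58 with no filter and 53 as means over cells. The 11 higher in CD8 T-like than NK-like barcodes became 18 with doublets kept. With 10 UMIs per gene, the 7 higher in NK-like became 15 and the 6 higher in regulatory T-like became 19, more genes being measured. With at least 1000 UMIs the log2 ratios of monocyte-like over neutrophil-like turned to 2.49 for Ccl3, 0.63 for Cd9, 1.33 for Cxcl3, 2.64 for Cxcl2, 1.56 for Egr1, 1.57 for Ncf1, 1.21 for Entpd1, 0.30 for Slc16a3, 3.51 for Ccl4 and 1.66 for Klf2, where that class held 26 and 71 barcodes, of which 15 and 22 were neutrophil-like before. Prf1 turned to 0.015 for CD8 T-like over NK-like with at least 1000 UMIs, and Ctss to 0.050 for CD8 T-like over regulatory T-like with doublets kept. Counting each of the other values once per alternative, 1960 comparisons with the reported value stayed within its interval and 197 moved. Except where given, the cause was not tested. No paired analysis was possible because there is 1 library per genotype. Small classes limit the depth: neutrophil-like barcodes of library 2 held 68446 UMIs, so that 3 UMIs are 43.8 CPM.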

Other observations

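Of the tests in this part, those of free RNA were set before their results were seen, and those of the other classes, of the cluster mix and of handling were chosen after. Migratory dendritic-like barcodes had the highest Rel level of any class named here, at 1979 CPM in library 1 (1503 to 2558) over 19 barcodes and 612 CPM in library 2 (246 to 1262) over 7. B-like barcodes of library 1 held 827 CPM (657 to 1028). Melanoma-like barcodes of the libraries differed in Cck, at 118 and 8.003 CPM, and Hspb1, a small heat shock protein, at 119 and 30.7 CPM.

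Rel was lower in monocyte-like and macrophage-like barcodes of library 2 than of library 1, and also in migratory dendritic-like barcodes (ratio 0.309, 0.119 to 0.679; 19 and 7 barcodes) and cluster 14 (0.697, 0.507 to 0.952). A difference in every class is argued against by the ratio of 1.12 in CD8 T-like barcodes (0.867 to 1.44). The ratio of 0.906 in melanoma-like barcodes (0.799 to 1.03) cannot weigh here, because that class was taken to lack Rel. Whether its Rel counts are background was not tested. Free melanoma RNA diluting Rel is argued against by its small share. Melanoma genes stood at 2.58% and 8.16% of their melanoma-like level in monocyte-like barcodes of libraries 1 and 2. In macrophage-like barcodes they stood at 2.55% and 7.36%. Subtracting melanoma RNA could therefore move the Rel ratio only a little. After it the ratio was 0.343 in monocyte-like and 0.216 in macrophage-like barcodes. A different mix of monocyte-like clusters is argued against, since the highest ratio within a cluster was 0.387, with an upper bound of 0.479. Genotype stays open and untested, because the barcodes name no genotype and a genotype read from the level of Rel would be circular, and pooled tumours and handling also differ between the libraries.

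The inflammatory cytokine list was lower in library 2 in monocyte-like and macrophage-like barcodes. It was also lower in neutrophil-like ones, at -1.59 over 4 genes (percentile 0.07), where the Rel ratio was 0.939 with a wide interval (0.337 to 2.44). Cd74 was at 57.5 and 1271 CPM in neutrophil-like barcodes of libraries 1 and 2, and a different make-up of that class was not tested. Free melanoma RNA diluting the list is argued against by the same small shares of melanoma RNA, whose subtraction could move the list only a little. After it the median log2 ratio of the list was -0.75 in monocyte-like and -0.96 in macrophage-like barcodes. Handling of the tissue cannot be told apart from the other differences between the libraries: the dissociation stress list lay under the median of all genes in 6 of 9 classes, and each library was handled once. Of the other 3 classes, plasmacytoid dendritic-like (median log2 ratio 0.14 over 4 genes, percentile 87.0) and NK-like (-0.12 against -0.14 for all genes, percentile 62.6) were exceptions, and low-UMI melanoma-like (0.20) held mostly copies of the other library and is not an independent one. Genotype stays open here too, as untested.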
